A study of Mus musculus with 7 samples.

How the data were processed

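Liver RNA of 7 mice was measured, 3 labelled as floxed controls and 4 as hepatocyte knockouts of Prkci, all after DEN and a 60% fat diet. Per the labels' protocols, RNA came from frozen tissue, poly(A) RNA was made into strand-specific libraries and these were read from a single end over 75 nt on a NextSeq 500. The deposited values are raw counts of reads per gene symbol, with 1 column per library, and 0 columns of per-sample values were left out. STAR, DESeq2 and the mm10 build are named in the submitters' processing notes without their roles or versions. The read counter and the gene annotation are not given in the sources used here, so how reads shared by near-identical genes were counted is unknown, and members of such families are called uncertain.

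The file used here holds 24421 gene symbols, 6729 of them at 0 in every library, and 2 entries that name no gene. The entry for reads in no feature took 8.62% to 16.3% of the reads of a library and that for ambiguous reads 0.433% to 0.575%, and both stayed out of library sizes and tests. Gene-assigned reads ran from 23807580 to 49203615 per library. At these depths 3 reads, the limit that a count of 0 allows, correspond to 0.061 to 0.126 CPM. Intervals and floors cover counting error only, since the reads carry no molecular identifiers. Symbols were matched to GENCODE release M21 on GRCm38, the same assembly as mm10, for coordinates and transcript lengths, 23376 by symbol and 669 by synonym, while 376 found no match.

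Groups were taken from the sample titles. The main test was edgeR 4.0.16 (R 4.3.3): TMM factors, genes kept by filterByExpr with its minimum count of 10, glmQLFit with robust estimation and the two-sided quasi-likelihood F test for genotype, with Benjamini-Hochberg adjustment over the 13638 genes tested and a threshold of 0.05. CPM are TMM-normalised, except that Xist is given without TMM factors. Standard errors are those of the log2 fold change in the edgeR fit. The p-values measure the spread between these mice. No replicate block was planned for the main test, and libraries with the same number did not deviate together. No pair of libraries within a group agreed within sampling noise (chi-square per degree of freedom at least 39).

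Gene lists, their tests, the main model, the rule for named genes and most alternatives were fixed before the data were examined. Of 43 lists, 40 were tested on log2 CPM with camera of limma 3.58.1 at a preset correlation of 0.01. The list of mitochondrially encoded subunits had no member in the file used here, the pancreatic acinar list had fewer than 5 tested members, and the sex-linked list served only as a check. For each list the members past the threshold over all genes and adjusted over the list alone were counted. Named genes were Prkci, and, among genes past the threshold with a mean log2 CPM above 1 and no overlap of the groups, the 12 with the largest rise and the 12 with the largest fall, without predicted or provisional symbols. For each list up to 4 members were named, the 2 with the smallest p that rose and the 2 that fell among those past either threshold, or the 2 most abundant where none passed. Some genes that the rule named are not reported here. Principal components used the 500 most variable genes.

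Alternatives were RLE and upper-quartile factors, DESeq2 1.42.0, limma-voom, edgeR without robust estimation, no low-count filter and a filter of 1 CPM in 4 libraries, a replicate block, each library left out in turn, other thresholds, a fold threshold of 1.2, and camera with an estimated correlation or fry for the lists. Thinning to equal depth, an acute phase score as covariate and leaving out controls 1 and 2 together were added after the data were seen. In the last of these, control 3 is assumed to vary like the libraries labelled knockout. The edgeR steps were tested on simulated data with 13482 genes, 200 of them changed, drawn from the means and depths of this comparison. Over 5 simulations they recovered 57.0% of the genes changed 2-fold and 85.8% of those changed 4-fold, and 7.76% of the calls were false. Genes were drawn independently and without a state shared by some libraries of a group, so these rates need not hold for the real data. Figures were drawn with matplotlib 3.10.9.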

Results

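The series holds poly(A) RNA-seq of liver from 7 C57BL/6 mice aged 36 weeks. The labels do not say whether the tissue was tumour or non-tumour liver, so the tumour content of each library is unknown. Each mouse had received diethylnitrosamine (DEN), a carcinogen that is activated in hepatocytes, at 25 mg/kg by intraperitoneal injection at 2 weeks of age, and then a diet with 60% fat for 32 weeks from 4 weeks of age. The labels name 3 controls that carry floxed Prkci alleles without Cre and 4 knockouts that also carry Alb-Cre, which is active in hepatocytes. Prkci encodes the atypical protein kinase C isoform lambda/iota, a kinase of the cell polarity complex. The series title asks about autophagy and oxidative phosphorylation, so both are given below with the other gene groups. Reads assigned to genes came to 23807580, 24935405 and 26556486 in controls 1 to 3 and to 49203615, 35198546, 28695455 and 37399081 in the libraries labelled knockout 1 to 4.

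Prkci transcript was not lower in the libraries labelled knockout. The gene (ENSMUSG00000037643.14, protein coding) lies on the plus strand of chromosome 3 from 30995747 to 31052959 in the mm10 assembly. It was at 23.3, 20.5 and 27.7 CPM, counts scaled to a common library size, in the controls, a mean of 23.8 ± 3.64 (SD, n = 3). In the libraries labelled knockout it was at 30.0, 30.7, 28.2 and 28.7 CPM, a mean of 29.4 ± 1.15 (SD, n = 4). The log2 fold change was 0.30 (SE 0.12), which did not pass edgeR's quasi-likelihood test after Benjamini-Hochberg adjustment (adjusted p = 0.214), although without control 3 it did (0.42, edgeR adjusted p = 0.0468). The direction of this count was not that of a loss. A count over the whole gene includes reads outside any deleted part, so it does not check the genotype labels either way. Every direction given below therefore rests on the labels alone.

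Control 3 stood apart from controls 1 and 2. The first principal component of the 500 most variable genes took 56.6% of the variance and placed controls 1 and 2 at -40.3 and -44.1, control 3 at -3.49 and the 4 libraries labelled knockout between 9.74 and 30.5. Saa1, which encodes the acute phase protein serum amyloid A1 and was chosen after its values were seen, was at 15130 and 16390 CPM in controls 1 and 2, at 474 CPM in control 3 and between 438 and 1097 CPM in the libraries labelled knockout. The 27 genes of the acute phase list took 11.5% and 11.8% of the reads in controls 1 and 2, against 4.34% in control 3 and 3.73% to 4.32% in the libraries labelled knockout. Control 3 correlated at 0.953 and 0.952 with controls 1 and 2 (Pearson's r of log2 CPM across genes, which are not independent replicates), and at 0.953 to 0.970 with the libraries labelled knockout.

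**Figure D1:**
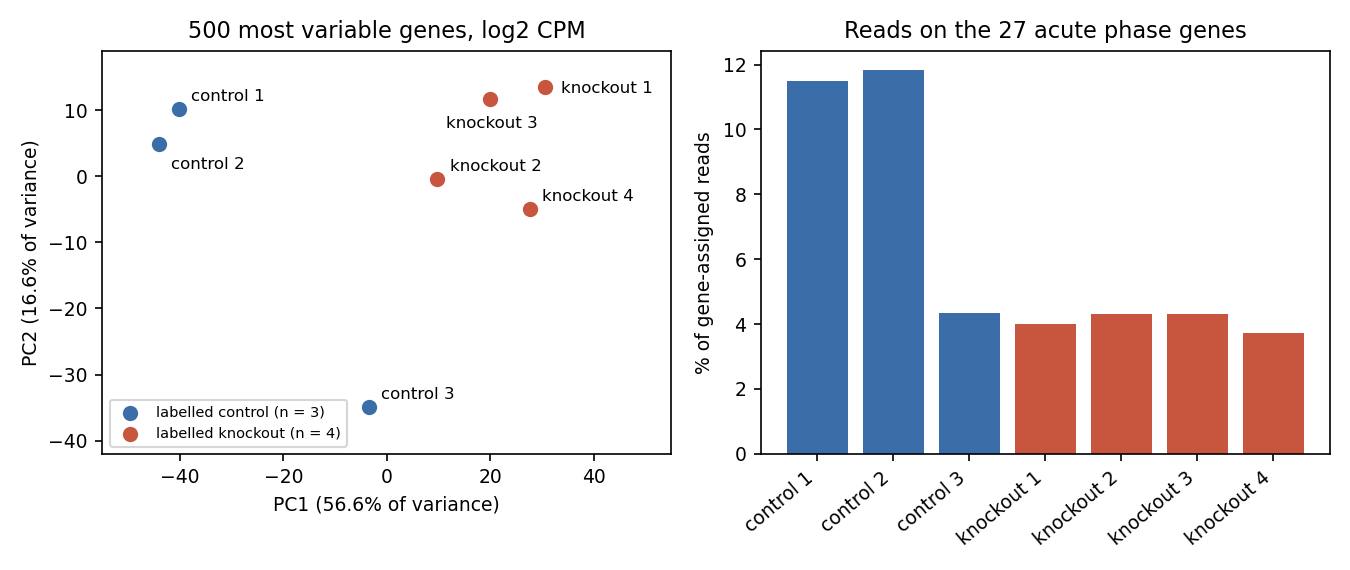
Left: positions of the 7 libraries on the first and second principal components (arbitrary units) of the 500 most variable genes, coloured by label. Right: percent of gene-assigned reads on the 27 acute phase genes, 11.5% and 11.8% in controls 1 and 2 and at most 4.34% in the other 5 libraries.

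Cap2, a cyclase-associated protein that acts on actin, rose in the libraries labelled knockout from 0.224 ± 0.202 CPM (SD, n = 3) to 10.5 ± 4.99 CPM (SD, n = 4), and the actin bundling protein Pls1 from 0.921 ± 0.160 to 8.81 ± 3.63 CPM. Ly6d, a GPI-anchored surface protein, rose from 12.4 ± 4.15 to 122 ± 45.2 CPM, and Ubd, a ubiquitin-like protein, from 3.09 ± 0.554 to 40.3 ± 16.5 CPM. Of the 13638 genes tested, 302 passed edgeR's quasi-likelihood test at a Benjamini-Hochberg adjusted p under 0.05, of which 172 were higher and 130 lower, 98 and 60 of them by more than 2-fold. None of the 302 had overlapping groups, and among all tested genes 16.3% did not overlap, against 5.71% by chance. The count fell to 36 without control 1, 31 without control 2, 77 without knockout 1, 55 without knockout 3 and 67 without knockout 4, and came to 1310 without control 3.

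Among the other genes of the largest rises were Sdcbp2 at a log2 fold change of 5.06 (SE 0.67), the fatty acid elongase Elovl7 at 4.13 (SE 0.60), the secreted semaphorin Sema3b at 3.77 (SE 0.74), the mitochondrial CoA transferase Sugct at 3.43 (SE 0.33) and Lrtm2 at 3.26 (SE 0.55). Gsta1, a glutathione S-transferase, had 1 read in all controls together and 1401 in the libraries labelled knockout, a depth-corrected ratio of 701 with a 95% counting interval of 126 to 27700. Gsta1 shares sequence with Gsta2, so its own level is uncertain. Sprr1a, a cornified envelope protein, had 1 read against 629, a ratio of 315 with a counting interval of 56.3 to 12500. The 12 largest rises had adjusted p-values from 0.00405 (Sugct) to 0.0414 (Sema3b) in edgeR's quasi-likelihood test.

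Mup7, a major urinary protein, fell in the libraries labelled knockout from 767 ± 147 CPM (SD, n = 3) to 6.58 ± 7.13 CPM (SD, n = 4), Mup14 from 187 ± 41.0 to 10.4 ± 3.58 CPM, Mup1 from 18.2 ± 8.70 to 0.671 ± 0.377 CPM and Mup9 from 29.9 ± 22.4 to 0.515 ± 0.402 CPM. Serpina1e, an alpha-1 antitrypsin, fell from 4426 ± 2696 to 164 ± 101 CPM. The Mup and Serpina1 genes are families of near-identical copies, so the level of each copy is uncertain. Avpr1a, the vasopressin receptor of hepatocytes, fell to 8.80 ± 1.55 CPM at a log2 fold change of -2.32 (SE 0.22), and Hhip, an inhibitor of hedgehog ligands, fell from 5.68 ± 0.908 to 0.411 ± 0.399 CPM.

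The other falls were the calpain Capn8 at a log2 fold change of -3.96 (SE 0.74), the carboxylesterase Ces4a at -3.53 (SE 0.64), the gelatinase Mmp9 at -2.89 (SE 0.57), the neurotrophin Ntf3 at -2.42 (SE 0.44) and the glutamate receptor Grm8 at -2.30 (SE 0.41). Adjusted p-values of the 12 falls ran from 0.00264 (Mup14) to 0.0492 (Capn8) in edgeR's quasi-likelihood test. Of these 24 rises and falls, 4 kept their call whichever library was left out, namely Sugct, Pls1, Mup14 and Avpr1a. Without control 1 and without control 2, 7 of the 24 passed in each case. With the acute phase score as covariate, chosen after the data were seen, 6 of the 24 passed.

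**Figure D2:**
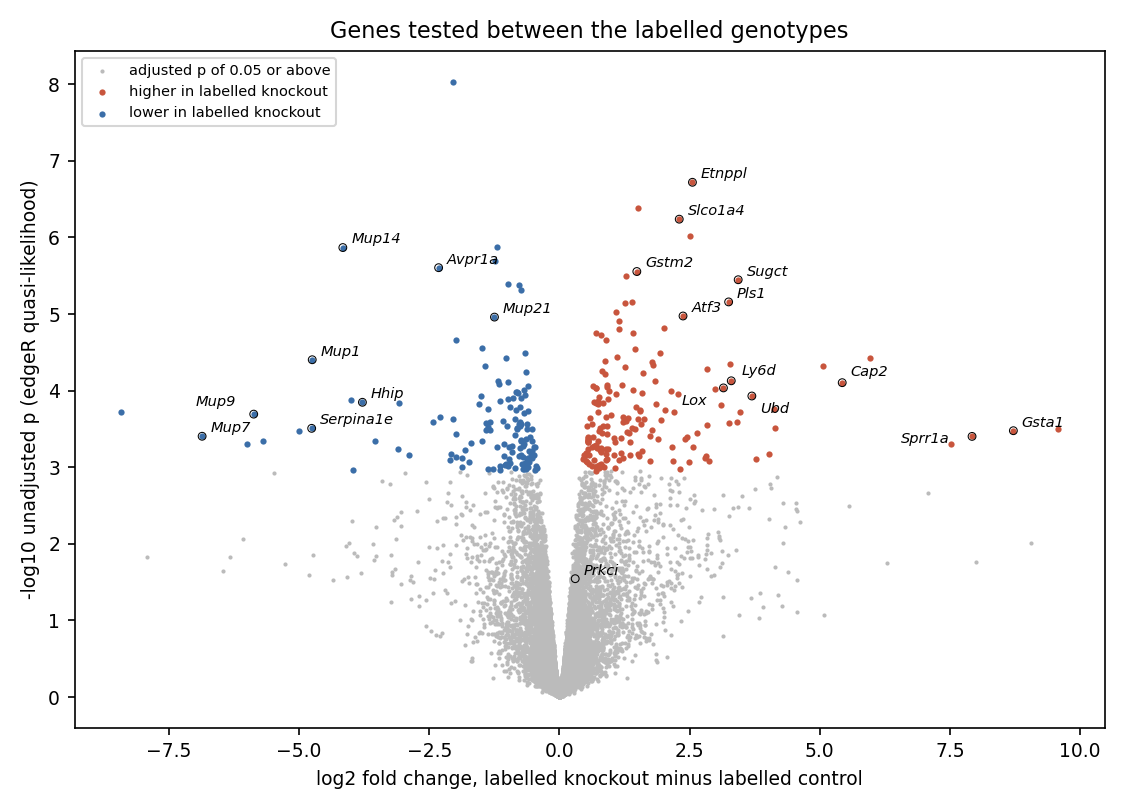
Log2 fold change (labelled knockout minus labelled control) against -log10 of the unadjusted p from edgeR's quasi-likelihood test for the 13638 tested genes. Coloured points are the 172 higher and 130 lower genes past an adjusted p of 0.05, and Prkci lies among the grey points at 0.30.

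Nuclear-encoded subunits of the respiratory chain, which carries out oxidative phosphorylation, were slightly higher on balance in 3 of the 4 libraries labelled knockout. Of 76 measured subunits, 71 had a log2 fold change above 0, and the list median was 0.20. Relative to the control mean, the mean log2 level of the list was 0.0116, -0.00781 and -0.00382 in controls 1 to 3, 0.0139 in knockout 1, which lay beside control 1, and 0.179, 0.371 and 0.120 in knockouts 2 to 4. No member passed edgeR's quasi-likelihood test over all genes, and 0 passed adjusted over the list alone, while 15 had an unadjusted p under 0.05, all higher, and 2 passed DESeq2 and 0 limma-voom. The ATP synthase subunits Atp5b, at 910 ± 43.2 CPM (SD, n = 3) against 1113 ± 63.3 CPM (SD, n = 4), and Atp5a1, at a log2 fold change of 0.18 (SE 0.13), were the most abundant members. As a set the list passed camera, which compares a list with the other genes at a preset correlation (adjusted p = 1.97e-06), but adjusted p = 0.597 with an estimated correlation.

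Core autophagy genes did not move together. Of 45 measured genes, 1 rose over all genes and 1 adjusted over the list alone, and 44 did not pass. The gene that rose was Map1lc3a, which encodes a precursor of the LC3 protein of autophagosome membranes, from 27.3 ± 4.99 CPM (SD, n = 3) to 47.0 ± 5.29 CPM (SD, n = 4; log2 fold change 0.78, SE 0.14, edgeR quasi-likelihood adjusted p = 0.0287). At an unadjusted p under 0.05, 2 members were higher and 6 lower, while 2 higher and 3 lower passed DESeq2 and 0 passed limma-voom. The list median was -0.01 (camera adjusted p = 0.523). The Map1lc3a call held in 2 of the 7 fits that each left out 1 library, with edgeR adjusted p-values from 0.00588 to 0.103.

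Of 50 measured lysosomal genes, 0 passed edgeR's quasi-likelihood test over all genes or adjusted over the list alone, with 14 at an unadjusted p under 0.05, 6 past DESeq2 and 0 past limma-voom. The most abundant members, Lamp2 and the protease Ctsb, had log2 fold changes of -0.16 (SE 0.14) and 0.07 (SE 0.16), and the list median was 0.00 (camera adjusted p = 0.854). With control 3 as the lone control it was 0.18 and with the acute phase score as covariate 0.15, both alternatives chosen after the data were seen, and there the list passed camera (adjusted p = 0.0272 and 0.0213). Among 21 regulators of mitochondrial biogenesis, 1 rose over all genes and 1 adjusted over the list alone, the nuclear receptor Esrra (log2 fold change 0.47, SE 0.10, edgeR adjusted p = 0.0414), with a median of -0.05 (camera adjusted p = 0.854). That call held in 1 of the 7 fits that left out 1 library, with edgeR adjusted p-values from 0.0226 to 0.158. Of 30 genes of the protein kinase C and polarity list, 1 rose over all genes and 2 adjusted over the list alone. Prkca, the classical isoform alpha, had a log2 fold change of 0.79 (SE 0.17, edgeR adjusted p = 0.0454), and Sqstm1, an adaptor that binds atypical protein kinase C, 0.58 (SE 0.14, edgeR adjusted p = 0.0655 over all genes). That list's median was -0.05 and its mean 0.01 (camera adjusted p = 0.975, direction lower), so the signs differed. The Prkca call held in 2 of the 7 fits that left out 1 library, with edgeR adjusted p-values from 0.00193 to 0.192.

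Targets of NRF2, the transcription factor that drives antioxidant and conjugation enzymes, were higher in the libraries labelled knockout. Of 41 measured, 4 rose over all genes, 37 did not pass, and 21 rose and 1 fell adjusted over the list alone. Gstm2, a glutathione S-transferase with close paralogs and therefore an uncertain level, rose from 27.2 ± 5.46 CPM (SD, n = 3) to 76.2 ± 9.47 CPM (SD, n = 4). The carbonyl reductase Cbr1 rose from 39.7 ± 8.39 to 92.9 ± 22.7 CPM. The member that fell adjusted over the list alone was Gstp1, from 343 ± 103 to 175 ± 44.8 CPM. The list median was 0.70 and no library labelled knockout overlapped a control in mean list level (camera adjusted p = 8.16e-12, and adjusted p = 0.397 with an estimated correlation). The median was 1.15 without control 3, but 0.48 with control 3 as the lone control and 0.49 with the acute phase score as covariate.

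Drug-metabolising enzymes rose in part. Of 29, 4 rose over all genes, and 12 rose and 2 fell adjusted over the list alone. The flavin monooxygenase Fmo2 had a log2 fold change of 1.54 (SE 0.25). The estrogen sulfotransferase Sult1e1, at -3.40 (SE 0.69), and Cyp2d9, at -0.65 (SE 0.18) and with close paralogs, were the members that fell adjusted over the list alone. The median was 0.62 (camera adjusted p = 0.00105, and adjusted p = 0.562 with an estimated correlation). It was 0.39 without control 1 and 0.37 without knockout 1. With control 3 as the lone control the median was 0.52 and with the acute phase score as covariate 0.47, and the camera call was lost in both (adjusted p = 0.0725 and 0.107).

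Genes with male-biased expression in liver fell in the libraries labelled knockout. Of 29 measured, 10 fell over all genes, 0 rose and 19 did not pass, and 17 fell adjusted over the list alone. Besides the Mup genes above, Mup21 fell from 171 ± 1.55 CPM (SD, n = 3) to 72.2 ± 16.2 CPM (SD, n = 4). The list median was -1.25, and the mean list level was lower in each library labelled knockout than in every control (camera adjusted p = 1.97e-11, and adjusted p = 0.397 with an estimated correlation). All 7 libraries held Y-linked transcripts, with Ddx3y between 84.0 and 122 CPM and Xist at most 0.521 CPM.

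Female-biased liver genes went both ways. Of 22, 3 rose over all genes, and 4 rose and 1 fell adjusted over the list alone. The organic anion transporter Slco1a4 rose from 16.5 ± 0.562 to 81.2 ± 19.4 CPM, and Fmo2 was also among those over all genes. The median was -0.20 whereas the mean was 0.25 and the direction of the camera test was higher (camera adjusted p = 0.236), so their signs differed. Without control 3 the median was 0.82 and with control 3 as the lone control 0.11, neither with a call (camera adjusted p = 0.123 and 0.835).

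Of 33 measured genes in the list of secreted hepatocyte proteins and hepatocyte transcription factors, 3 fell over all genes, and 1 rose and 13 fell adjusted over the list alone. Serpina1c fell from 2617 ± 475 CPM (SD, n = 3) to 977 ± 197 CPM (SD, n = 4) and Serpina1a from 1498 ± 230 to 779 ± 59.9 CPM, both with near-identical copies and uncertain. The other was the transcription factor Foxa3, chosen after its values were seen (log2 fold change -0.69, SE 0.14, edgeR quasi-likelihood adjusted p = 0.0356). The nuclear receptor Nr1i2, at 85.3 ± 12.6 against 116 ± 16.5 CPM, was the member that rose adjusted over the list alone. The list median was -0.43 (camera adjusted p = 2.56e-05, and adjusted p = 0.397 with an estimated correlation). With the acute phase score as covariate it was -0.14, and with control 3 as the lone control it was -0.07 and the camera call was lost (adjusted p = 0.0815).

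Markers of the liver zones split. Of 24 periportal genes, 2 rose over all genes, and 3 rose and 1 fell adjusted over the list alone. Etnppl, an ethanolamine phosphate phospholyase, rose from 19.7 ± 3.63 CPM (SD, n = 3) to 116 ± 25.0 CPM (SD, n = 4), and the glycine cleavage enzyme Gldc from 187 ± 13.6 to 271 ± 18.2 CPM. The protease Ctsc, at a log2 fold change of -0.85 (SE 0.21), fell adjusted over the list alone. The median was 0.27 (camera adjusted p = 0.00606, and adjusted p = 0.562 with an estimated correlation), and without control 3 or knockout 2 the camera call was lost (adjusted p = 0.201 and 0.0639). With control 3 as the lone control the median was 0.60.

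Of 23 pericentral genes, 1 rose and 1 fell over all genes, and 3 rose and 3 fell adjusted over the list alone. The cation transporter Slc22a3 rose (log2 fold change 1.45, SE 0.27) and Cyp2c50, with close paralogs, fell (-1.03, SE 0.22). The pericentral median was -0.45 (camera adjusted p = 0.0154, and adjusted p = 0.597 with an estimated correlation), and without control 3 or knockout 3 the camera call was lost (adjusted p = 0.137 and 0.0682).

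**Figure D3:**
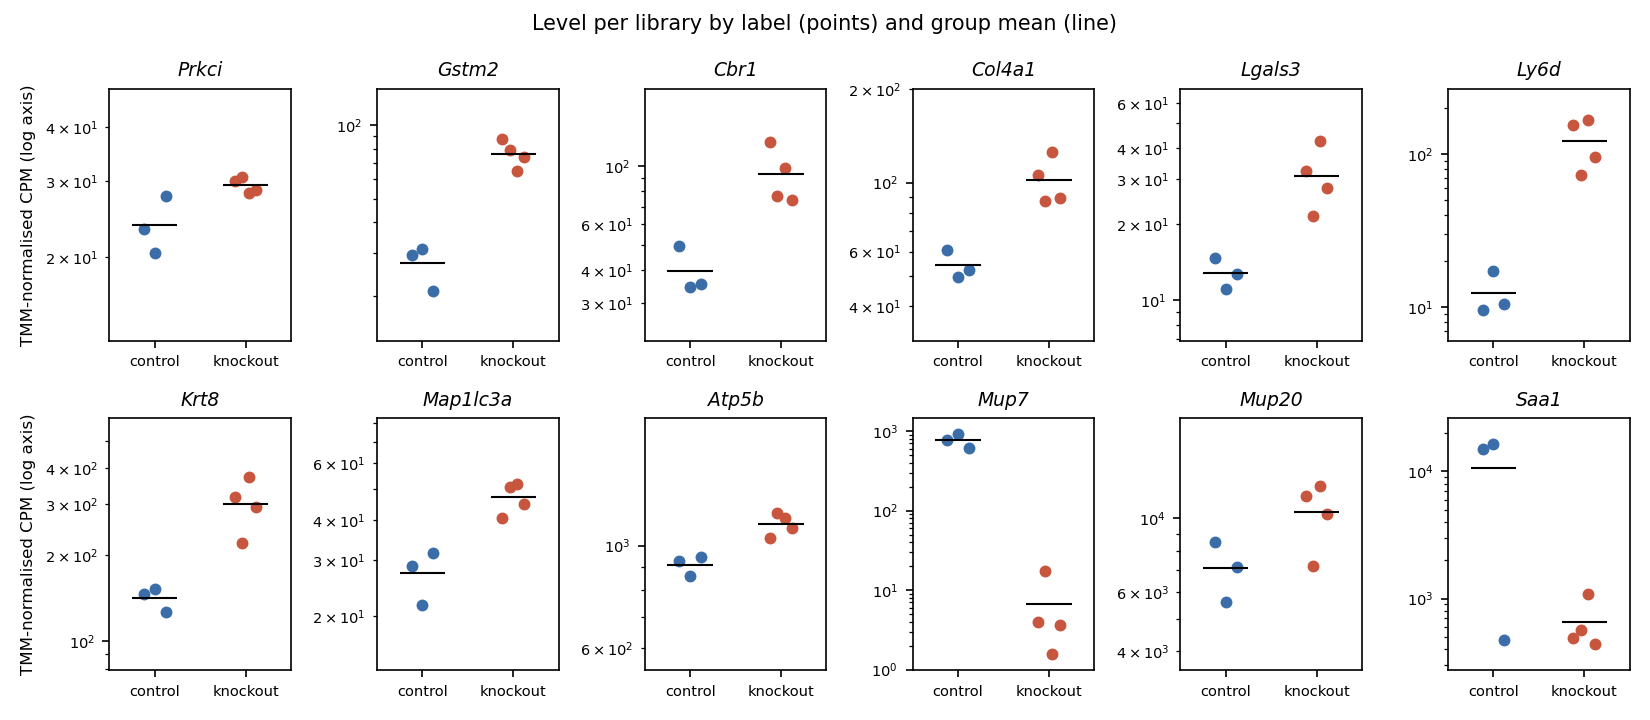
TMM-normalised CPM (log axis) of 12 genes in each library by label, with the group mean as a line. The 4 libraries labelled knockout lie above all controls for Prkci, Gstm2, Cbr1, Col4a1, Lgals3, Ly6d, Krt8, Map1lc3a and Atp5b and below them for Mup7, while Mup20 and Saa1, chosen after their values were seen, overlap.

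Fatty acid oxidation genes differed in direction between the comparison with all controls and that with control 3. Of 41 measured, 0 passed edgeR's quasi-likelihood test over all genes or adjusted over the list alone, with 5 at an unadjusted p under 0.05, 1 past DESeq2 and 0 past limma-voom. The list median was 0.31 (camera adjusted p = 0.000325, and adjusted p = 0.733 with an estimated correlation). With control 3 as the lone control the median was -0.29 (camera adjusted p = 4.98e-05), so the direction turned. It was 0.16 without control 1, 0.65 without control 3 and 0.11 without control 2, where the camera call was lost (adjusted p = 0.088).

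Of 33 lipogenic genes, 0 passed edgeR's quasi-likelihood test in either way of adjusting, over all genes or adjusted over the list alone, with 7 at an unadjusted p under 0.05, 5 past DESeq2 and 0 past limma-voom. The desaturase Scd1 was at 3905 ± 3360 CPM (SD, n = 3) against 6090 ± 1503 CPM (SD, n = 4), and the lipid droplet protein Plin2 had a log2 fold change of 0.35 (SE 0.28). The lipogenic median was 0.29 (camera adjusted p = 0.0384, and adjusted p = 0.597 with an estimated correlation). The median was 0.12 without control 1, 0.13 without control 3, 0.33 without knockout 2 and 0.13 without knockout 3. The call was lost without control 1, knockout 2 or knockout 3 (camera adjusted p = 0.412, 0.078 and 0.0822), with control 3 as the lone control (0.149) and with the acute phase score as covariate (0.0968).

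The other metabolic lists did not pass camera with all libraries. Of 25 cholesterol synthesis genes 0 passed edgeR's quasi-likelihood test over all genes or adjusted over the list alone, with 2 at an unadjusted p under 0.05, 2 past DESeq2 and 0 past limma-voom, and a median of -0.24 (camera adjusted p = 0.0993). Sc5d had a log2 fold change of -0.39 (SE 0.20). That list passed camera without control 3, knockout 1 or knockout 3 (medians of -0.32, -0.31 and -0.28, camera adjusted p = 0.0106, 0.0151 and 0.029), whereas its median was 0.03 without control 2 and 0.29 with control 3 as the lone control. Of 25 bile acid genes, 1 rose over all genes, Slco1a4, and 4 rose and 5 fell adjusted over the list alone. Among them were the repressor Nr0b2 at 1.10 (SE 0.24), the bile acid importer Slc10a1 at -0.71 (SE 0.17) and the hydroxylase Cyp7b1 at -1.79 (SE 0.39), with a list median of -0.10 (camera adjusted p = 0.607), but 0.07 without control 3. Of 20 gluconeogenesis and insulin genes, 0 passed over all genes in edgeR's quasi-likelihood test, with 7 at an unadjusted p under 0.05, 2 past DESeq2 and 0 past limma-voom. Adjusted over the list alone, 1 rose, the pseudokinase Trib3 (1.46, SE 0.32), and 2 fell, Irs2 (-1.03, SE 0.25) and Akt2 (-0.30, SE 0.09), with a median of -0.17 (camera adjusted p = 0.607), but 0.23 with control 3 as the lone control. Of 27 glycolysis and hypoxia genes 0 passed edgeR's quasi-likelihood test over all genes or adjusted over the list alone, with 5 at an unadjusted p under 0.05, 3 past DESeq2 and 0 past limma-voom. Ldha was at -0.43 (SE 0.15), Tpi1 at -0.10 (SE 0.17) and the median at 0.00 (camera adjusted p = 0.81).

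Extracellular matrix genes rose in the libraries labelled knockout. Of 41 measured, 8 rose over all genes, 33 did not pass, and 22 rose and 1 fell adjusted over the list alone. The basement membrane collagen Col4a1 rose from 54.3 ± 5.89 CPM (SD, n = 3) to 102 ± 17.6 CPM (SD, n = 4), and Lox, which cross-links collagen, from 0.281 ± 0.112 to 2.50 ± 1.04 CPM. Fibronectin, Fn1, which hepatocytes also secrete into plasma, was the member that fell adjusted over the list alone (log2 fold change -1.08, SE 0.26). The list median was 0.80 and no libraries overlapped in mean level (camera adjusted p = 2.04e-10, and adjusted p = 0.459 with an estimated correlation), and with control 3 as the lone control the median was 0.50. Stellate cell markers went the other way. Of 24, 3 fell over all genes and 5 adjusted over the list alone, among them Hhip, above, and Colec10, a collectin, from 51.1 ± 11.7 to 19.2 ± 5.42 CPM. The stellate median was -0.29 (camera adjusted p = 0.0319, and adjusted p = 0.597 with an estimated correlation), and without control 3 or knockout 2 the call was lost (camera adjusted p = 0.486 and 0.078). It was -0.15 without control 3 and -0.56 with control 3 as the lone control.

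Of 32 oncofetal and liver tumour genes, 2 rose over all genes, and 5 rose and 1 fell adjusted over the list alone. Ly6d, above, and the guidance receptor Robo1, from 12.7 ± 3.20 CPM (SD, n = 3) to 33.6 ± 4.17 CPM (SD, n = 4), were the genes that rose. Gulo, an enzyme of ascorbate synthesis, fell adjusted over the list alone (log2 fold change -0.72, SE 0.17). The median was 0.56 (camera adjusted p = 0.0237, and adjusted p = 0.648 with an estimated correlation), but 0.01 without knockout 1 and 1.08 with control 3 as the lone control, and the call was lost without control 1, control 3 or knockout 1 (camera adjusted p = 0.0665, 0.414 and 0.134). Of 48 proliferation genes, 0 passed edgeR's quasi-likelihood test over all genes or adjusted over the list alone, with 8 at an unadjusted p under 0.05, 4 past DESeq2 and 0 past limma-voom. Ccnd1 had a log2 fold change of 0.53 (SE 0.36) and Pcna -0.05 (SE 0.12). The proliferation median was 0.48 (camera adjusted p = 0.0207, and adjusted p = 0.733 with an estimated correlation), but 0.18 without control 3 and 0.24 without knockout 1, where the call was lost (camera adjusted p = 0.512 and 0.107), and 0.81 with control 3 as the lone control. Of 27 p53 and DNA damage genes, 0 passed over all genes in edgeR's quasi-likelihood test, with 7 at an unadjusted p under 0.05, 6 past DESeq2 and 0 past limma-voom. Adjusted over the list alone 5 rose, among them the stress cytokine Gdf15, at 8.14 ± 1.14 CPM (SD, n = 3) against 18.8 ± 6.54 CPM (SD, n = 4), and Gadd45b, at a log2 fold change of 1.62 (SE 0.38), and the median was 0.28 (camera adjusted p = 0.000602, and adjusted p = 0.397 with an estimated correlation).

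**Figure D4:**
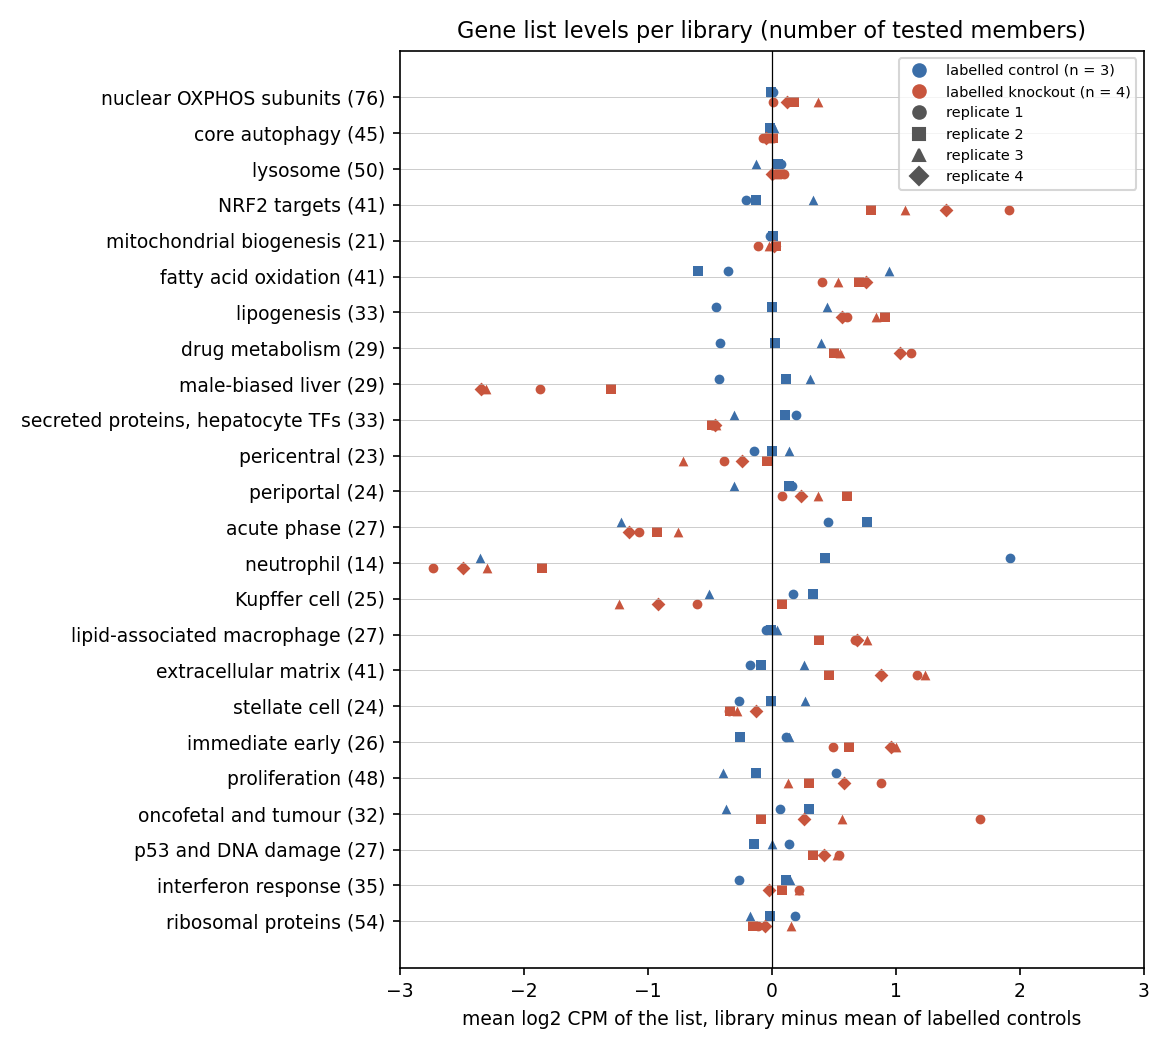
Mean log2 CPM of 24 gene lists in each library, relative to the mean of the labelled controls, with marker shape giving the replicate number and the number of measured members in brackets. Male-biased liver genes lie lower in all 4 libraries labelled knockout than in any control and NRF2 targets higher, while in the acute phase and neutrophil lists control 3 lies beside the libraries labelled knockout.

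Immediate early genes, which respond within minutes to stress or growth signals, rose. Of 26, 5 rose over all genes and 7 adjusted over the list alone, among them Atf3, from 2.39 ± 0.584 CPM (SD, n = 3) to 12.5 ± 3.87 CPM (SD, n = 4), and Egr2, from 0.182 ± 0.080 to 1.84 ± 0.327 CPM. The median was 0.54 (camera adjusted p = 1.11e-05, and adjusted p = 0.397 with an estimated correlation). It was 0.86 without control 3, but 0.36 without knockout 4, 0.43 with control 3 as the lone control and 0.41 with the acute phase score as covariate. Of 30 endoplasmic reticulum and integrated stress genes, 1 rose over all genes, Atf3. Adjusted over the list alone 2 rose, Atf3 and Trib3, and 1 fell, the transcription factor Xbp1 (log2 fold change -0.66, SE 0.17), with a median of 0.16 (camera adjusted p = 0.147). That list passed camera without knockout 1 (median 0.28, camera adjusted p = 0.0243), and its median was -0.08 without knockout 3.

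The medians of the acute phase and neutrophil lists were lower with all controls, but differed little with control 3 as the lone control. The members named here, Serpina3k, Itih4, Mmp9 and Cxcr2, were nevertheless higher in control 3 than in every library labelled knockout. Serpina3k was at 8481 CPM in control 3, against 2527 to 5274 CPM in the libraries labelled knockout. Of 27 acute phase genes, 3 fell over all genes and 16 adjusted over the list alone. Serpina3k, with close paralogs and uncertain, fell from 9092 ± 540 CPM (SD, n = 3) to 3258 ± 1345 CPM (SD, n = 4), and Itih4 from 8955 ± 4648 to 2703 ± 314 CPM. The median was -1.25 (camera adjusted p = 4.35e-07, and adjusted p = 0.562 with an estimated correlation), and with control 3 as the lone control it was 0.11 (camera adjusted p = 0.33). Of 14 neutrophil genes, 1 fell over all genes, Mmp9, and 10 adjusted over the list alone, including the chemokine receptor Cxcr2 (-1.86, SE 0.46). Mmp9 was at 11.9 CPM in control 1, against 3.38 and 2.28 CPM in controls 2 and 3. Its call held in 1 of the 7 fits that left out 1 library, with log2 fold changes from -3.28 to -1.84. The neutrophil median was -2.97 (camera adjusted p = 2.56e-05, and adjusted p = 0.562 with an estimated correlation), but it was -1.84 without control 1, and with control 3 as the lone control -0.09 (camera adjusted p = 0.409).

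Macrophage lists moved apart. Of 27 markers of lipid-associated and recruited macrophages, 1 rose over all genes, and 9 rose and 3 fell adjusted over the list alone. Lgals3 (galectin 3) rose from 12.8 ± 1.81 CPM (SD, n = 3) to 31.1 ± 8.93 CPM (SD, n = 4), and the integrin Itgax had a log2 fold change of 1.45 (SE 0.33). Ly6c2, at -1.53 (SE 0.46), and Itgam, at -1.34 (SE 0.44), both also found in monocytes and neutrophils, fell adjusted over the list alone. In control 3, however, they were at 1.07 and 4.81 CPM, within the ranges of the libraries labelled knockout (0.945 to 1.41 and 3.99 to 5.56 CPM). The median was 0.76 (camera adjusted p = 0.000276, and adjusted p = 0.397 with an estimated correlation), and 0.50 with control 3 as the lone control. Of 25 Kupffer cell markers, 0 passed edgeR's quasi-likelihood test over all genes or adjusted over the list alone, with 7 at an unadjusted p under 0.05, 3 past DESeq2 and 1 past limma-voom. Slc40a1, the iron exporter, had a log2 fold change of 0.61 (SE 0.22) and Cd5l -0.38 (SE 0.37). The Kupffer median was -0.39 (camera adjusted p = 0.00597, and adjusted p = 0.733 with an estimated correlation), and the call was lost without control 1 or control 2 (camera adjusted p = 0.0533 and 0.0553). The Kupffer median was -0.26 without control 2 and -0.62 without control 3. With control 3 as the lone control it was 0.13, so the direction turned.

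Of 27 endothelial markers, 0 passed over all genes in edgeR's quasi-likelihood test, with 8 at an unadjusted p under 0.05, 2 past DESeq2 and 0 past limma-voom. Adjusted over the list alone 1 fell, the sinusoidal receptor Gpr182 (log2 fold change -0.55, SE 0.13), and the median was -0.16 (camera adjusted p = 0.0151, and adjusted p = 0.597 with an estimated correlation), with the call lost without control 1 or control 3 (camera adjusted p = 0.0533 and 0.0713) and with control 3 as the lone control (0.0975). The endothelial median was -0.26 without control 3 and -0.11 without knockout 3. Of 12 adipocyte markers, 1 fell over all genes, the beta-3 adrenergic receptor Adrb3 (-1.37, SE 0.29), and 2 rose and 2 fell adjusted over the list alone. The lipase Pnpla2 had a log2 fold change of 0.43 (SE 0.12) and the water and glycerol channel Aqp7 4.05 (SE 0.95). For Aqp7 the controls held 0, 0 and 5 reads and the libraries labelled knockout 105, 53, 24 and 24, so the size of its rise is uncertain. The adipocyte median was 0.59 (camera adjusted p = 0.0198, and adjusted p = 0.397 with an estimated correlation), but with control 3 as the lone control 0.35 and without a call. It was 1.08 without control 3 and 0.37 without knockout 2, and with the acute phase score as covariate the call was lost (camera adjusted p = 0.174). Of 21 cholangiocyte markers, 1 rose over all genes, and 3 rose and 2 fell adjusted over the list alone. Krt8, a keratin that hepatocytes also express, rose from 142 ± 13.2 CPM (SD, n = 3) to 301 ± 64.1 CPM (SD, n = 4). St14 had a log2 fold change of 1.96 (SE 0.45), and Ambp, a hepatocyte product, -1.07 (SE 0.30). Ambp in control 3, at 2195 CPM, lay within the range of the libraries labelled knockout (1838 to 2356 CPM). The cholangiocyte median was 0.00 (camera adjusted p = 0.821).

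The remaining lists did not pass camera with all libraries. Of 29 cytokine genes, 1 rose over all genes, the NF-kappaB inhibitor Tnfaip3 (log2 fold change 0.85, SE 0.19), and 4 rose and 1 fell adjusted over the list alone, among them Relb (0.90, SE 0.20) and Cxcl12 (-0.55, SE 0.13). The cytokine median was 0.03 (camera adjusted p = 0.334). Of 12 B and plasma cell markers 0 passed over all genes in edgeR's quasi-likelihood test, with 2 at an unadjusted p under 0.05, 2 past DESeq2 and 0 past limma-voom. Adjusted over the list alone 2 fell, Mzb1 (-1.89, SE 0.51) and Xbp1, above, and the median was -0.23 (camera adjusted p = 0.172), with a call without control 2 (-0.32, camera adjusted p = 0.0356). No gene passed edgeR's quasi-likelihood test over all genes or adjusted over the list alone in the lists for interferon response, T and NK cells, MHC class I, circadian clock, ribosomal proteins or erythroid cells. Of 35 interferon genes, 5 had an unadjusted p under 0.05, 2 passed DESeq2 and 0 limma-voom, with Iigp1 at -0.24 (SE 0.21), Bst2 at 0.06 (SE 0.15) and a median of 0.01 (camera adjusted p = 0.854). Of 21 T and NK cell markers, 3 had an unadjusted p under 0.05 and 0 passed DESeq2 or limma-voom, with Zap70 at 0.47 (SE 0.37), Tox at 0.06 (SE 0.30) and a median of 0.08 (camera adjusted p = 0.365). Without control 2 that list passed camera (median 0.35, camera adjusted p = 0.043), and without knockout 2 its median was -0.09. Of 16 MHC class I genes, 1 had an unadjusted p under 0.05 and 0 passed DESeq2 or limma-voom, with B2m at 0.12 (SE 0.17), H2-K1, with close paralogs, at 0.22 (SE 0.15) and a median of 0.09 (camera adjusted p = 0.53). Of 20 clock genes, 6 had an unadjusted p under 0.05, 2 passed DESeq2 and 0 limma-voom, with Tef at -0.21 (SE 0.11), Bhlhe40 at -0.22 (SE 0.16) and a median of 0.15 (camera adjusted p = 0.854). Of 54 ribosomal protein genes, 2 had an unadjusted p under 0.05 and 0 passed DESeq2 or limma-voom, with Rpl4 at -0.17 (SE 0.15), Rps3 at -0.03 (SE 0.16) and a median of -0.06 (camera adjusted p = 0.228). That list passed camera as lower without control 3 or knockout 3 (-0.15 and -0.13, camera adjusted p = 0.0039 and 0.00837) and as higher with control 3 as the lone control (0.17, camera adjusted p = 0.0404). Of 5 erythroid genes, 1 had an unadjusted p under 0.05 and 0 passed DESeq2 or limma-voom, with Alas2 at 0.40 (SE 0.13), Klf1 at -0.52 (SE 0.38) and a median of -0.52 (camera adjusted p = 0.854), but 5.79 with control 3 as the lone control, also without a call (camera adjusted p = 0.288).

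Across the 40 lists tested, 21 passed camera, 13 higher and 8 lower, and 11 of the 21 had no overlap of the libraries in mean list level. With an estimated correlation 0 passed camera, with 3 at an unadjusted p under 0.05, and 6 passed fry, which asks whether a list's own genes move 1 way on balance and does not compare it with other genes. The 6 were the NRF2, male-biased, secreted hepatocyte, lipid-associated macrophage, p53 and adipocyte lists, with fry adjusted p-values of 0.0337 to 0.0408.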

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

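The tests of control 3's position, all 3 tests for male-biased genes and the test of the acute phase state for OXPHOS genes were chosen only after the result was seen, as were thinning to equal depth and the fits that adjust for or leave out controls 1 and 2. Among the 4 libraries labelled knockout, 6 of 149 named values, list levels and library measures had a library whose gap to the nearest other, as a share of the group's range, was beyond Dixon's 95% critical value, and chance marks about 5%. Knockout 2 was lowest for Ubd (gap share 0.938) and highest for Mup9 (0.935), Ly6c2 (0.882) and Serpina3k (0.939). Knockout 3 was lowest for Avpr1a (0.893) and knockout 4 lowest for Fmo2 (0.877).

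Of the 35 splits of the 7 libraries into 3 and 4, only the labelled one passed as many as 302 genes, with 22 as the highest of the others. A share of 1 in 35 splits is the smallest the design allows, so it argues against chance without excluding it. For the 21 lists that passed camera chance is not excluded. The labelled split was the only 1 of the 35 with as many, but other splits gave 20, 19 and 19 lists. The number of lists thus barely exceeded that of other splits, and with an estimated correlation 0 passed camera (3 at an unadjusted p under 0.05). The greater depth of the libraries labelled knockout is excluded as the whole cause, since 93.3% of the 302 genes that could still be tested stayed called with every library thinned to equal depth. An acute phase response in controls 1 and 2 may account for part of the count, since among 1293 genes called without control 3, control 3 lay at a median of 0.293 (interquartile range -0.02 to 0.605) from the libraries labelled knockout (0) to controls 1 and 2 (1), so genotype and acute phase state cannot be told apart for these genes with 1 control outside that state.

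The fall of male-biased liver genes in the libraries labelled knockout was weighed next. Female animals are excluded, since the lowest level of Ddx3y or Eif2s3y in these libraries was 59.4 CPM, and the acute phase state is excluded as the whole cause, since control 3 lay 1.60 log2 units above the highest of them, more than their range of 1.05. Reads shared between near-identical copies remain open for the 13 members of the Mup, Serpina1, Cyp4a12 and Cyp2d families (median log2 fold change -3.58, 8 called). The 16 other members lie outside these families, but were not checked for close copies of their own. Their median was -1.07, but only 2 of these were called, C6 and Susd4, so the families and the rest cannot be told apart by this test. A lower male pattern of expression with loss of the kinase is a candidate explanation that was not tested, because Prkci transcript does not check the genotype labels.

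The higher level of nuclear OXPHOS genes in the libraries labelled knockout was small, at a median of 0.20, and uneven, with the mean list level at 0.0139 above the control mean in knockout 1, beside control 1 at 0.0116, and at 0.371 in knockout 3. Short transcripts are excluded as the cause, since 0 of 10000 random lists matched on expression and transcript length had a median as high (their median was 0.03). The acute phase state of controls 1 and 2 is excluded as the whole cause, since the median was 0.18 with control 3 as the lone control. The members move together (estimated correlation 0.407), so a shared difference between these mice that is not genotype remains possible, and with that correlation the list did not pass camera (adjusted p = 0.597). A link to the genotype stays a hypothesis.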

How the results depend on the processing

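Thinning, the acute phase covariate and leaving out controls 1 and 2 together were chosen after seeing the data, and the other settings were planned. The 302 called genes, where tested, kept their direction under every setting that refitted the genes, which their lack of overlap favours. Both other scalings moved the median log2 fold change of all genes by less than 0.1. The count of genes past the threshold was 1136 with DESeq2, which gave 287 genes no adjusted p, 137 with limma-voom, 27 and 767 at adjusted p thresholds of 0.01 and 0.1, and 113 with glmTreat against a fold change of 1.2. It ranged from 31 (without control 2) to 1310 (without control 3) with 1 library left out, was 68 with the acute phase score as covariate and 9 with both controls 1 and 2 left out, where the median absolute log2 fold change of the 302 genes was 0.92 in each, against 1.07 with all libraries and no covariate, and the cause was not tested, except that the last fits have fewer libraries or degrees of freedom. The share of called genes that were higher was 50.3% without control 3, 67.7% without control 2 and 72.7% without knockout 1, against 57.0% with all libraries.

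The replicate numbers of the titles did not pair the libraries. Same-number libraries had correlations of deviations of -0.05, 0.07 and -0.14, and control 3 deviated most like knockout 4 (0.217). The replicate block could use only libraries whose number occurs in both groups, so knockout 4 was left out. With the block, 76 genes and 22 lists passed, against 67 and 21 without knockout 4 and without a block. The fall from 302 genes was thus also seen without the block. The log2 fold change of Prkci ranged from 0.21 (without control 2) to 0.42 (without control 3, edgeR adjusted p = 0.0468), and the cause was not tested. For the gene list tests, 0 lists passed with the estimated correlation and 6 with fry. The OXPHOS median of 0.20 is the same value in both by construction, since the fold changes are those of the main fit. The loss of the list's call was not fixed in this way (camera adjusted p = 0.597 with an estimated correlation, fry adjusted p = 0.216). The first principal component took 49.0% of the variance with a larger set of the most variable genes and 45.0% with all tested genes.

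Among lists that passed camera with all libraries or under the setting compared, 4 medians turned direction, all when controls 1 and 2 counted less. With the acute phase score as covariate the fatty acid oxidation median was -0.24, Kupffer 0.14, acute phase 0.0449 and ribosomal protein 0.17, and with controls 1 and 2 left out -0.29, 0.13, 0.11 and 0.17. The score was the mean of the acute phase genes themselves, so their median near 0 with that covariate was fixed in advance. Controls 1 and 2 were left out for their high level of these genes, so that turn is no independent result either. Lists that passed in neither fit also changed sign. In these settings the cholesterol synthesis median went from -0.24 to 0.27 and 0.29, gluconeogenesis from -0.17 to 0.23 in both and erythroid, over 5 genes, from -0.52 to 5.90 and 5.79. With 1 library left out, signs also changed for female-biased (0.82), bile acid (0.07), endoplasmic reticulum stress (-0.08), T and NK cell (-0.09), cholesterol synthesis (0.03) and ribosomal protein (0.06) genes and for lists with medians near 0. The cause was not tested. No depth limit was seen for the total count, which was 313 in libraries thinned to 23807580 reads, while genes under about 0.126 CPM could not be measured in the shallowest library.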

Other observations

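The gene groups in this part, and the test of them, were chosen only after the result was seen; the test of genes near Prkci was not. The annexin, complement and tricarboxylic acid cycle groups were put together after their genes were seen, so their counts and medians restate that choice and are no independent evidence of a direction. Of 28 annexins, galectins, S100 proteins and intermediate filament genes, 11 passed edgeR's quasi-likelihood test upwards over all genes, 17 did not pass, and 6 had a log2 fold change below 0. Anxa2 rose by a log2 fold change of 1.79 (SE 0.23), Anxa5 from 91.1 ± 5.01 CPM (SD, n = 3) to 218 ± 38.7 CPM (SD, n = 4) and the intermediate filament protein vimentin, Vim, from 32.5 ± 3.34 to 59.4 ± 7.29 CPM. The group's median log2 fold change was 0.56 (adjusted p = 0.125 with an estimated correlation), and 0.70 with control 3 as the lone control.

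Of 25 complement components, 5 fell over all genes and 20 did not pass in edgeR's quasi-likelihood test, and the 5 were C8b, from 359 ± 89.2 CPM (SD, n = 3) to 128 ± 26.7 CPM (SD, n = 4), C8a, C6, Masp1 and C1rl. The median of -0.69 (adjusted p = 0.136 with an estimated correlation) was -0.20 with control 3 as the lone control. Of 15 enzymes of the tricarboxylic acid cycle, 2 rose over all genes, among them Idh2 from 63.5 ± 11.8 to 108 ± 2.89 CPM, with a median of 0.23 (adjusted p = 0.136 with an estimated correlation). Of 77 mitochondrial ribosomal proteins, 0 passed edgeR's quasi-likelihood test, with 5 at an unadjusted p under 0.05, 2 past DESeq2 and 0 past limma-voom, and a median of 0.02 (camera adjusted p = 0.927).

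The summed level of the 13 Mup genes did not fall as that of the 12 genes other than Mup20 did. It was 13940 ± 932 CPM (SD, n = 3) in the controls and 11950 ± 1850 CPM (SD, n = 4) in the libraries labelled knockout (two-sided exact permutation p = 0.171). Mup20 was at 7078 ± 1460 against 10420 ± 2350 CPM (exact p = 0.114), and the sum of the other 12 genes at 6864 ± 695 against 1522 ± 529 CPM (exact p = 0.0286, the smallest this design allows, and 0.0572 adjusted over 4 such tests). Mup20 took 50.5% ± 7.51 of the Mup reads in the controls and 86.5% ± 7.31 in the libraries labelled knockout (exact p = 0.0286).

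Called genes near Prkci on chromosome 3 were counted as a check for sequence carried along with the floxed allele. Per the labels both groups carry floxed alleles, so such sequence should be shared and the test does not bear on it. Within 10 Mb, 1 of 53 tested genes was called (1.89%), against 2.20% of the other genes (one-sided Fisher's exact p = 0.692). The exact 95% binomial interval of the first share ran from 0.0478% to 10.1%, so 53 genes are too few to exclude a cluster of called genes there. A share under 2 times that of the other genes had been set beforehand as excluding it, which was too loose because it put no bound on the interval. Over 21 chromosomes no share of called genes passed a two-sided Fisher's exact test after adjustment (lowest adjusted p = 0.596).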
